A study of Mus musculus with 12 samples.

How the data were processed

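RNA was measured by bulk sequencing in 12 libraries, 7 from mouse chronic proximal thoracic aortic aneurysms (cPTAA) and 5 from sham-operated proximal thoracic aortas. Groups and library numbers were taken from the sample titles. The titles number the samples one by one but do not name animals, so p-values measure the spread between these samples. Per the labels, all animals were male and of one strain, and the aneurysms followed periaortic elastase together with BAPN. A sequencing batch was not given in the sources used here. Elastase, BAPN and the surgery that went with them could be compared with sham only as one condition.

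Per the labels' protocols, total RNA was extracted, messenger RNA was captured on oligo-dT beads and fragmented, and the first strand was primed with random hexamers. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and StringTie were used with the genome build GRCm39, and the role of StringTie was not given. The strand setting, the scaling of the reads and any filter were not given in the sources used here. Without a stated strand setting, genes that overlap on opposite strands cannot be told apart in these values.

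The deposited values are a signal per gene that is never negative. Checked on the values, the deposited signal was a whole number of reads divided by one factor per library: 100% of the values were whole within 0.02 reads, and the largest deviation was 0.000311 reads. The values are called normalised read counts here. The table lists 30130 genes, each with at least 2 reads over the 12 libraries. Recovered totals ranged from 14078885 to 17493428 reads, so 1 read was worth between 0.8631 and 1.164 units. Intervals for shares of reads are Wilson 95% intervals and cover counting error only.

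The design fixed before the data were examined named a count test for counts and limma for normalised values. Since the deposited values are normalised, the test was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(value + 1). It was run for the 21415 genes with a value of 1 or more in at least 5 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Changes of at least 2-fold were tested with limma's treat against a log2 fold change of 1. The 45 gene lists, also fixed before the data were examined, were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives, and a range given beside a list's p is that of camera at the preset correlation over its other settings. A list score is the mean of log2(value + 1) over the measured members. Spread was compared by the distance of each library to the mean of the others of its group over the 1000 most variable genes, with a two-sided exact permutation test. The 4 relations between list scores used Pearson's r and Spearman's rho with two-sided exact permutation p over pairings.

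Genes were named by a rule fixed with the design. It takes the 8 largest rises and the 8 largest falls among protein-coding genes past the threshold, with a mean of at least 10 in the higher group and no overlap between the groups. It adds a panel of 16 genes and the members of each list with the smallest p. Where 5 or fewer members of a list moved in one direction they are named as well, and those outside the rule were chosen after their values were seen. Biotypes came by symbol from the GENCODE M21 annotation, which matched 28641 of the listed genes. That annotation is of another build than the one in the processing notes, so no coordinates are printed. The result of the platelet marker list is not reported here, though the list is counted in the totals over lists.

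The calculations were tested on simulated data with 200 changed genes. For the simulated comparison of cPTAA with sham, limma recovered 0% of genes changed 1.5-fold (22645 genes tested), 30% of those changed 2-fold (22657 tested) and 88.5% of those changed 4-fold (22598 tested). Of its calls at 2-fold and 4-fold, 9.09% and 5.85% were false. The 0% false at 1.5-fold is uninformative, since no changed gene was recovered there. Of the 45 simulated lists, camera called 1, the one that was shifted 2-fold. The simulated genes were drawn independently of each other. In the real data the estimated correlation within a list reached 0.964, for the respiratory chain, so the simulation cannot show how often camera calls correlated lists falsely. As an added alternative, the quasi-likelihood test of edgeR 4.0.16 on the recovered reads called 2622 genes higher and 2260 lower of 15839 tested. Both tools called 4452 genes in common, 0 of them with opposite sign. Other alternatives were DESeq2 1.42.0, other scalings and filters, voom with sample weights, a pseudocount of 0.1, and leaving out each library. The edgeR test with TMM, TMM scaling under limma, a fit without cPTAA 6, 7 and 9 and sham 8, and a fit with the brown adipocyte score as a covariate were chosen after seeing the data.

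Some values are uncertain. Tagln, an abundant smooth muscle gene, had 255 to 1512 reads in cPTAA and 423 to 631 in sham. Gapdh had 90 to 4650 and 87 to 1616. Neither was read on its own as a level of expression. Both stayed in their lists for counts, scores and tests, Tagln in the contractile list and Gapdh in the glycolysis list. Members of the immunoglobulin, MHC, Saa, haemoglobin, guanylate-binding protein and Klra families can share reads with close copies and are uncertain in the same way.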

Results

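Chronic aneurysms of the proximal thoracic aorta were compared with sham-operated aortas by RNA sequencing of whole tissue. The model combined elastase applied around the aorta, a protease that degrades elastic fibres, with BAPN, an inhibitor of lysyl oxidases. There were 7 cPTAA libraries (numbered 2, 3, 4, 6, 7, 9 and 12) and 5 sham libraries (1, 5, 8, 10 and 11). Depth was 16.2 ± 0.879 M reads in cPTAA (SD, n = 7) and 15.7 ± 1.20 M in sham (SD, n = 5). Values below are normalised read counts as mean ± SD over the 7 cPTAA and 5 sham libraries, and log2 fold changes are cPTAA minus sham ± SE with limma adjusted p. No pair of libraries within a group was close enough to be 1 library deposited again (lowest chi-square per degree of freedom 20.5), so each was counted once. The first 3 principal components held 39.6%, 26.5% and 14% of the variance.

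The aneurysms differed from sham in 5128 of 21415 tested genes. Of these, 2754 rose and 2374 fell, and 7654 genes had an unadjusted p under 0.05. Among tested genes, 13% had no overlap between the 7 and 5 values, where chance gives 0.253%. The median log2 fold change of all tested genes was -0.0537. The share that rose was 53.7% of the calls, and 66.7% (3348 rose, 1670 fell) when reads were scaled to library totals alone with edgeR. By voom with sample weights falls outnumbered rises, with 49% rising (3406 rose, 3552 fell). With the brown adipocyte score as a covariate, chosen after seeing the data, 663 genes rose and 374 fell, so that 63.9% rose. That covariate also widened the errors, with a median SE over the tested genes of 0.464 against 0.302 without it.

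The 8 largest rises by the fixed rule, which takes protein-coding genes, were in Saa3, Igfbp2, Spp1, Klra2, Thbs1, Cthrc1, Dio3 and Col8a1. Some immunoglobulin genes, which have another biotype, had larger log2 fold changes, such as Ighg1 (8.003 ± 0.95), chosen after its values were seen. Saa3, an acute phase protein whose values are uncertain because of close copies, was at 1607 ± 2148 against 8.37 ± 8.25 (log2 fold change 6.54 ± 0.92, adjusted p = 0.000131). Igfbp2, which binds insulin-like growth factors, was at 48134 ± 29146 against 711 ± 375 (log2 fold change 5.85 ± 0.54, adjusted p = 6.44e-06). The matricellular genes Spp1 (osteopontin), Thbs1 (thrombospondin) and Cthrc1 were at 12618 ± 8557 against 298 ± 212, 36642 ± 27338 against 877 ± 477 and 1203 ± 1006 against 27.4 ± 9.96. Their log2 fold changes were 5.43 ± 0.47, 5.11 ± 0.61 and 5.11 ± 0.50. Col8a1, a short-chain collagen of the vessel wall, was at 13639 ± 8804 against 356 ± 175 (log2 fold change 5.04 ± 0.51, adjusted p = 1.11e-05). Dio3, which inactivates thyroid hormone, and Klra2, a lectin-like receptor with close copies, had log2 fold changes of 5.06 ± 0.52 and 5.14 ± 0.60.

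The 8 largest falls by that rule were in genes of several kinds. Sgk2, a kinase, was at 3.48 ± 2.18 against 98.3 ± 65.3 (log2 fold change -4.31 ± 0.50, adjusted p = 2.99e-05), and the calpain gene Capn13 at 0.674 ± 1.08 against 32.9 ± 31.5 (log2 fold change -4.13 ± 0.55, adjusted p = 8.51e-05). Hhip, which binds hedgehog ligands, was at 30.3 ± 22.8 against 303 ± 106 (log2 fold change -3.83 ± 0.70, adjusted p = 0.00103). Slc27a2, a fatty acid transporter and acyl-CoA synthetase, was at 241 ± 246 against 2456 ± 777 (log2 fold change -3.68 ± 0.45, adjusted p = 4.46e-05). Cyp2b10, Mmd2, the homeobox gene Hoxb8 and the mitochondrially encoded mt-Nd4l had log2 fold changes of -3.45 ± 0.51, -3.33 ± 0.44, -4.06 ± 0.65 and -3.39 ± 0.42. Once the brown adipocyte score was a covariate, Cyp2b10 and Mmd2 no longer passed (log2 fold changes of -1.43 and -1.72 against -3.45 and -3.33 without it, adjusted p from 0.0818 to 0.151, and at most 0.00104 under the other alternatives).

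Genes of the elastic fibre and of collagen were higher in the aneurysms. Eln (elastin) was at 83320 ± 30030 against 25844 ± 3555 (log2 fold change 1.57 ± 0.35, adjusted p = 0.00475), Fbn1 (fibrillin) at 13034 ± 5750.2 against 4398 ± 727 (log2 fold change 1.41 ± 0.34, adjusted p = 0.00678), and Fbln5 and Ltbp2 had log2 fold changes of 1.66 ± 0.21 and 2.596 ± 0.24. Among elastic fibre and microfibril genes, 11 of 16 rose and 0 fell (12 and 0 adjusted over the list alone). The elastic fibre list had a camera adjusted p of 4.26e-07 (adjusted p = 0.0923 with an estimated correlation). The collagens Col1a1, at 16954 ± 14044 against 4254 ± 863 (log2 fold change 1.76 ± 0.35, adjusted p = 0.00189), Col3a1, at 63864 ± 30303 against 20144 ± 6271 (log2 fold change 1.595 ± 0.34, adjusted p = 0.00334), and Col5a2, at 16282 ± 8080 against 3718 ± 496, were higher. Of the fibrillar collagens, 6 of 9 rose and 0 fell (7 and 1 adjusted over the list alone) (camera adjusted p = 0.00103, and adjusted p = 0.318 with an estimated correlation), and 1 fell without sham 1 or sham 5 and by edgeR. Lox, an enzyme of the family that BAPN inhibits, was at 11266 ± 6087 against 1896 ± 258 (log2 fold change 2.35 ± 0.38, adjusted p = 0.000442), and P4ha3 and Fkbp10, both of collagen processing, had log2 fold changes of 4.97 ± 0.48 and 1.003 ± 0.12. Across lysyl oxidases and collagen processing enzymes, 14 of 24 rose and 1 fell (17 and 1 adjusted over the list alone), the fall being Pcolce2, an enhancer of procollagen processing, which did not pass without cPTAA 6, 7 and 9 and sham 8 (0 falls). The crosslinking list had a camera adjusted p of 1.91e-08 (adjusted p = 0.191 with an estimated correlation). Of the matricellular proteins and proteoglycans, 19 of 23 rose and 1 fell (19 and 1 adjusted over the list alone), the fall being Ogn, a small proteoglycan. The matricellular list had a camera adjusted p of 8.50e-11 (adjusted p = 0.146 with an estimated correlation). Of the basement membrane genes, 1 of 19 rose and 1 fell (1 and 1 adjusted over the list alone), the rise being Nid2 and the fall Col4a6. The basement membrane list had a camera adjusted p of 0.637 (adjusted p = 0.881 with an estimated correlation). Basement membrane counts moved with the libraries, with 2 rises without cPTAA 6 and by edgeR, 4 without cPTAA 6, 7 and 9 and sham 8, 3 rises without cPTAA 9, 3 falls without cPTAA 4 and 2 falls without sham 1. The brown adipocyte score was lower in cPTAA (8.48 ± 1.10 against 10.91 ± 0.65), and with it as a covariate 3 elastic fibre, 0 fibrillar collagen, 3 crosslinking and 6 matricellular genes rose. The elastic fibre, crosslinking and matricellular lists kept their calls, with mean log2 changes of 0.57, 0.28 and 0.98 against 1.13, 0.98 and 1.98 without it (adjusted p at most 0.0191, range 2.68e-12 to 8.53e-06). The fibrillar collagen list then lost its call (mean log2 change -0.20, adjusted p = 0.958, range 0.000195 to 0.00472) and the basement membrane list gained one as lower (mean log2 change -0.48, adjusted p = 0.011, range 0.377 to 0.859). In that fit Eln, Fbn1, Col1a1, Col3a1, Col5a2, Lox, Nid2 and Col4a6 no longer passed (log2 fold changes of 0.61, 0.34, 0.42, 0.38, 0.66, 0.94, 0.16 and -0.91 against 1.57, 1.41, 1.76, 1.595, 1.96, 2.35, 1.31 and -1.400 without it, adjusted p from 0.151 to 0.802, and at most 0.0231 under the other alternatives).

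**Figure D1:**
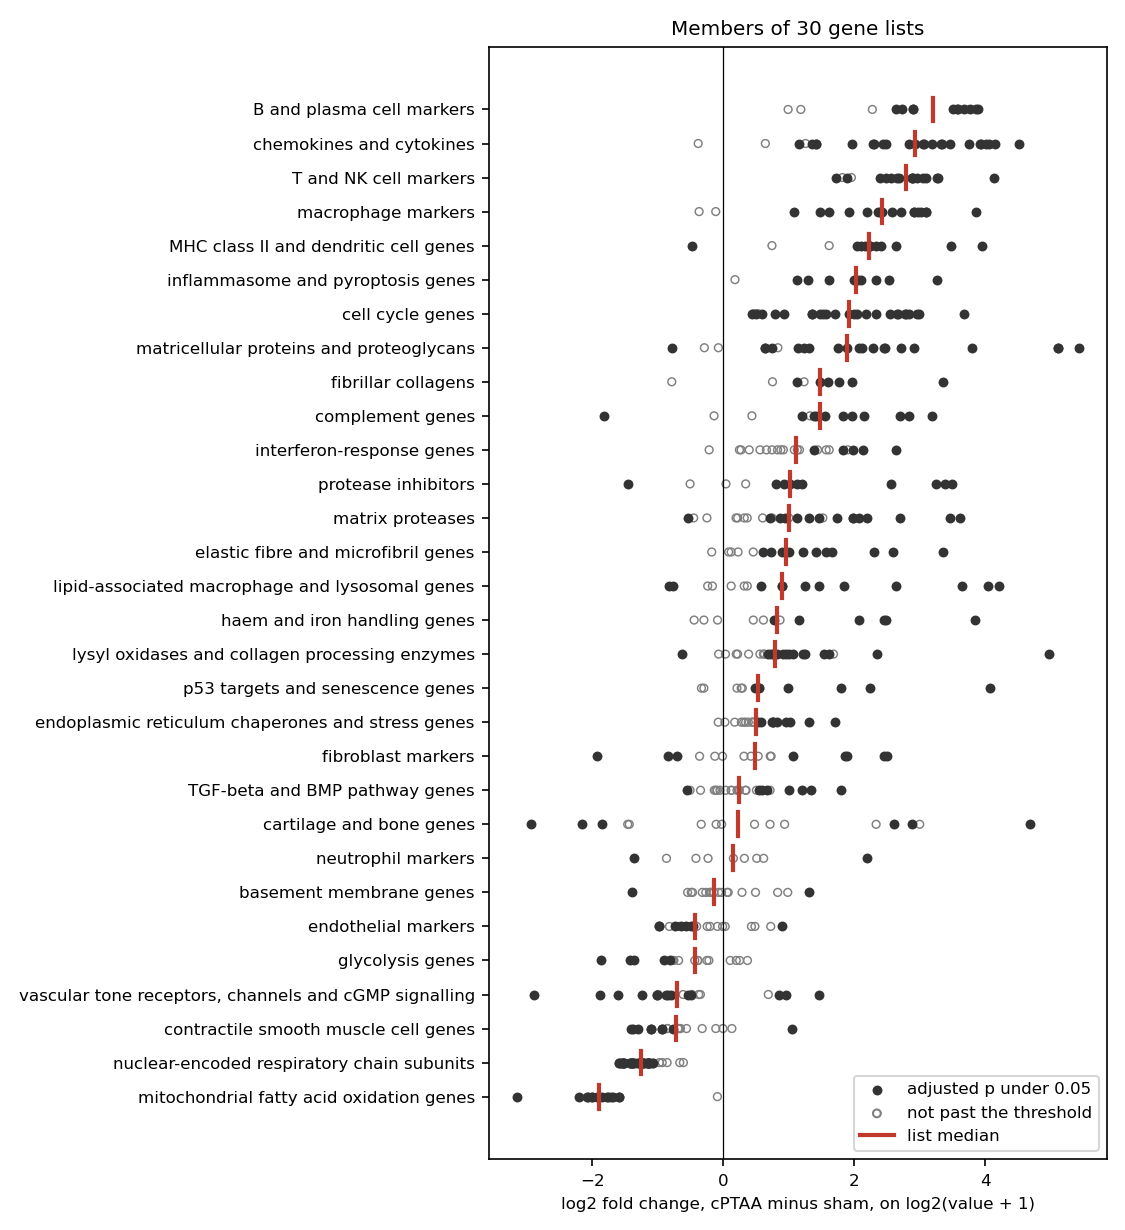
Each point is a tested member of one of the main gene lists, placed by its log2 fold change (cPTAA minus sham, on log2(value + 1)). Filled points had an adjusted p under 0.05, open points did not, and the bar is the list median, from -1.90 for fatty acid oxidation to 3.20 for B and plasma cell markers.

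Matrix-degrading proteases and their inhibitors were both higher. Mmp12, the macrophage elastase, was at 711 ± 456 against 65.03 ± 60.6 (log2 fold change 3.62 ± 0.46, adjusted p = 5.81e-05), and Mmp2, a gelatinase, at 6305 ± 2918 against 1506 ± 576 (log2 fold change 1.98 ± 0.37, adjusted p = 0.00125). The cathepsins Ctss and Ctsk had log2 fold changes of 3.45 ± 0.31 and 2.19 ± 0.25. Mmp9, the other gelatinase, did not pass, at 129.8 ± 53.7 against 98.5 ± 32.96 (log2 fold change 0.32 ± 0.35, adjusted p = 0.55), and its sign turned with the brown adipocyte score as a covariate (-0.03). Of the matrix proteases, 14 of 25 rose and 1 fell (16 and 1 adjusted over the list alone). The protease list had a camera adjusted p of 2.78e-07 (adjusted p = 0.148 with an estimated correlation). The fall, Mmp17, a membrane-bound metalloproteinase, was lost (0 falls) without any one of cPTAA 3, 6, 9 and 12 and sham 5, 8, 10 and 11, and without cPTAA 6, 7 and 9 and sham 8. Timp1, an inhibitor of matrix metalloproteinases, was at 3662 ± 1661 against 309 ± 86.2 (log2 fold change 3.48 ± 0.28, adjusted p = 3.08e-06), and Serpina3n had a log2 fold change of 3.24 ± 0.43. Among protease inhibitors 9 of 13 rose and 1 fell (9 and 1 adjusted over the list alone), the fall being Timp4. The protease inhibitor list had a camera adjusted p of 5.73e-05 (adjusted p = 0.086 with an estimated correlation). In the fit with the brown adipocyte score, 5 proteases and 3 inhibitors rose and 0 of either fell. Both lists kept their calls, with mean log2 changes of 0.54 and 1.10 against 1.19 and 1.24 without it (adjusted p at most 0.00664, range 9.23e-09 to 0.000233). In that fit Mmp2 no longer passed (log2 fold change of 0.62 against 1.98 without it, adjusted p = 0.409, and at most 0.0055 under the other alternatives).

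Markers of macrophages and their mediators were higher together. Cd68 was at 1657 ± 581 against 192 ± 69.03 (log2 fold change 3.09 ± 0.27, adjusted p = 4.95e-06), Adgre1 (F4/80) at 2413 ± 637 against 306 ± 115 and Ms4a7 at 916 ± 294 against 62.2 ± 20.6. Of the macrophage markers, 17 of 19 rose and 0 fell (17 and 0 adjusted over the list alone). The macrophage list had a camera adjusted p of 6.01e-15 (adjusted p = 0.0923 with an estimated correlation). Trem2, a lipid-sensing receptor of macrophages, was at 824 ± 284 against 49.7 ± 21.1 (log2 fold change 4.04 ± 0.29, adjusted p = 2.22e-06), and Itgax and Lgals3 had log2 fold changes of 3.65 ± 0.40 and 2.63 ± 0.35. In the lipid-associated and lysosomal list, 10 of 17 rose and 2 fell (10 and 2 adjusted over the list alone), the falls being Plin2 and Acp5. The lipid-associated list had a camera adjusted p of 0.000105 (adjusted p = 0.148 with an estimated correlation). Plin2 coats lipid droplets and Acp5 is a phosphatase, and 1 fall was left without any one of cPTAA 2, 3, 4, 6, 7 and 12 and sham 1, 5, 10 and 11, and 1 with TMM scaling. The monocyte chemokine Ccl2 was at 489 ± 289 against 25.5 ± 10.4 (log2 fold change 4.06 ± 0.46, adjusted p = 2.59e-05), Il1b at 163 ± 108 against 13.7 ± 6.80 (log2 fold change 3.33 ± 0.43, adjusted p = 6.45e-05), and Cxcl16 had a log2 fold change of 2.84 ± 0.25. Of the chemokines and cytokines, 24 of 27 rose and 0 fell (24 and 0 adjusted over the list alone). The cytokine list had a camera adjusted p of 6.05e-17 (adjusted p = 0.0923 with an estimated correlation). Neutrophil markers did not pass as a list, where 1 of 9 rose and 1 fell (1 and 0 adjusted over the list alone). The neutrophil list had a camera adjusted p of 0.717 (adjusted p = 0.881 with an estimated correlation). The neutrophil rise was Csf3r and the fall Hdc, which was lost (0 falls) without any one of cPTAA 3, 4, 6 and 7 and sham 1, 8 and 11. With the brown adipocyte score as a covariate, 12 macrophage, 7 lipid-associated and 17 cytokine genes rose, and 0 genes of the lipid-associated list fell. These lists kept their calls, with mean log2 changes of 1.94, 1.31 and 3.03 against 2.22, 1.19 and 2.66 without it (camera adjusted p at most 4.7e-06, range 4.01e-19 to 0.00376). Csf3r no longer passed in that fit (log2 fold change of 1.75 against 2.200 without it, adjusted p = 0.0874, and at most 0.00143 under the other alternatives). Hdc, which makes histamine, had an adjusted p of 0.0747 in that fit (log2 fold change -2.39 against -1.36 without it) and up to 0.195 in the others, where it also did not pass without a filter (0.0587), with a pseudocount of 0.1 (0.0507) or without haemoglobin and mitochondrial genes (0.0558).

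Complement and inflammasome genes followed the same direction. Pycard and Casp4, of the inflammasome pathways, had log2 fold changes of 2.06 ± 0.23 and 1.61 ± 0.18, and in their list 9 of 10 rose and 0 fell (9 and 0 adjusted over the list alone). The inflammasome list had a camera adjusted p of 1.91e-08 (adjusted p = 0.0923 with an estimated correlation). The anaphylatoxin receptors C3ar1 and C5ar1 were at 1341 ± 422 against 151 ± 64.9 and 830.2 ± 259 against 118 ± 44.1. Among complement genes 10 of 14 rose and 1 fell (11 and 1 adjusted over the list alone), the fall being C7, a part of the terminal pathway. The complement list had a camera adjusted p of 3.73e-07 (adjusted p = 0.148 with an estimated correlation). Under the brown adipocyte covariate, 4 inflammasome and 4 complement genes rose, and both lists kept their calls, with mean log2 changes of 1.61 and 1.02 against 1.85 and 1.43 without it (adjusted p at most 0.000229, range 5.99e-09 to 8.53e-06).

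Lymphocyte and antigen presentation genes were higher as well. Klrb1c and Il2rb, of NK and T cells, were at 25.9 ± 10.1 against 1.02 ± 2.28 and 182 ± 61.3 against 34.5 ± 15.8. For T and NK cell markers, 16 of 18 rose and 0 fell (18 and 0 adjusted over the list alone). The T and NK cell list had a camera adjusted p of 8.28e-12 (adjusted p = 0.101 with an estimated correlation). The B cell genes Blk and Cd79b were at 102 ± 89.7 against 5.80 ± 4.42 (log2 fold change 3.89 ± 0.54, adjusted p = 0.000114) and 202 ± 191 against 13.1 ± 6.45 (log2 fold change 3.503 ± 0.57, adjusted p = 0.000455). Of the B and plasma cell markers, some of them immunoglobulin genes with close copies, 11 of 14 rose and 0 fell (12 and 0 adjusted over the list alone). The B and plasma cell list had a camera adjusted p of 2.78e-07 (adjusted p = 0.191 with an estimated correlation). H2-DMb1, of the MHC class II loading machinery, and Ccr7, a homing receptor, had log2 fold changes of 2.100 ± 0.28 and 3.94 ± 0.54. In the list of MHC class II and dendritic cell genes, 11 of 14 rose and 1 fell (13 and 1 adjusted over the list alone), the fall being Zbtb46, a transcription factor of dendritic cells. The MHC class II list had a camera adjusted p of 2.38e-08 (adjusted p = 0.148 with an estimated correlation). Interferon-response genes moved in part: 5 of 22 rose and 0 fell (12 and 0 adjusted over the list alone) (camera adjusted p = 0.000122, and adjusted p = 0.482 with an estimated correlation), and the rises were Oasl2, Oas1a, Mx1, Ifi44 and Zbp1, with Mx1 at 359 ± 172 against 65.8 ± 49.7 (log2 fold change 2.64 ± 0.48, adjusted p = 0.00102). That number of rises was 3 without cPTAA 2, 4, 6 or 9 or sham 8, 2 without sham 10 or sham 11, 8 without cPTAA 7, 10 without cPTAA 12, 12 without sham 1 and 11 without sham 5, and edgeR gave 3. The interferon list's call was lost without cPTAA 6, 7 and 9 and sham 8 together (adjusted p = 0.0714, range 1.23e-06 to 0.0714; 2 rises) and by fry (adjusted p = 0.108). With the brown adipocyte score as a covariate, 6 T and NK, 0 B and plasma cell, 2 MHC class II and 0 interferon genes rose, and 0 MHC class II and dendritic cell genes fell. The lists kept their calls, with mean log2 changes of 2.75, 1.36, 1.45 and 1.78 against 2.70, 2.96, 2.12 and 1.14 without it (adjusted p at most 0.0121, range 1.97e-13 to 0.0714), in that order. In that fit Blk, Cd79b, Mx1 and Oas1a no longer passed (log2 fold changes of 2.36, 2.45, 2.64 and 2.48 against 3.89, 3.503, 2.64 and 2.14 without it, adjusted p from 0.0757 to 0.122, and at most 0.0268 under the other alternatives).

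Cell cycle and stress genes were higher. Mcm3, of the replicative helicase, was at 385 ± 60.5 against 151 ± 28.1 (log2 fold change 1.35 ± 0.16, adjusted p = 3.49e-05) and Cdk1, the mitotic kinase, at 107 ± 49.1 against 14.8 ± 7.08 (log2 fold change 2.78 ± 0.36, adjusted p = 7.31e-05). Of the cell cycle genes, 25 of 27 rose and 0 fell (26 and 0 adjusted over the list alone). The cell cycle list had a camera adjusted p of 4.28e-15 (adjusted p = 0.142 with an estimated correlation). The cell cycle inhibitor Cdkn2b and the stress-induced cytokine Gdf15 were at 269 ± 65.5 against 75.1 ± 9.63 and 71.4 ± 12.2 against 14.8 ± 4.48. Among p53 targets and senescence genes 7 of 13 rose and 0 fell (7 and 0 adjusted over the list alone) (camera adjusted p = 0.000275, and adjusted p = 0.086 with an estimated correlation), with 1 fall without cPTAA 6, 7 and 9 and sham 8. Sdf2l1 and Dnajb11, of the endoplasmic reticulum, had log2 fold changes of 1.71 ± 0.20 and 0.75 ± 0.11, and in their list 10 of 20 rose and 0 fell (11 and 0 adjusted over the list alone). The endoplasmic reticulum list had a camera adjusted p of 2.50e-06 (adjusted p = 0.148 with an estimated correlation). Hmox1 (haem oxygenase) and Slc11a1, a metal transporter of macrophages, had log2 fold changes of 2.07 ± 0.24 and 2.44 ± 0.18, and of haem and iron handling genes 6 of 12 rose and 0 fell (6 and 0 adjusted over the list alone). The haem and iron list had a camera adjusted p of 0.000724 (adjusted p = 0.191 with an estimated correlation). Once the brown adipocyte score was a covariate, 1 cell cycle, 4 p53 and 5 endoplasmic reticulum genes rose. The 3 lists kept their calls, with mean log2 changes of 0.90, 0.78 and 0.55 against 1.83, 0.87 and 0.60 without it (adjusted p at most 0.000694, range 2.20e-16 to 0.00169). In that fit Cdk1 no longer passed (log2 fold change of 1.61 against 2.78 without it, adjusted p = 0.0724, and at most 0.000356 under the other alternatives).

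Contractile genes fell in part. Myh11, the smooth muscle myosin heavy chain, was at 34217 ± 18171 against 74348 ± 9771 (log2 fold change -1.305 ± 0.38, adjusted p = 0.0208). Without sham 5 its adjusted p was 0.0506, the highest of its alternatives apart from the brown adipocyte covariate, and the lowest was 0.00457. Actg2 and Synpo2 had log2 fold changes of -1.41 ± 0.32 and -1.39 ± 0.32. Acta2, the smooth muscle actin, did not pass, at 122700 ± 51075 against 141220 ± 23075 (log2 fold change -0.32 ± 0.42, adjusted p = 0.627), and its sign turned with the brown adipocyte score as a covariate (0.50). Of the contractile smooth muscle genes, 1 of 20 rose and 8 fell (1 and 12 adjusted over the list alone), the rise being Sncg, a synuclein (camera adjusted p = 0.00134, and adjusted p = 0.434 with an estimated correlation, and fry adjusted p = 0.0559). The number of falls was 5 without any one of cPTAA 3, cPTAA 12, sham 8, sham 10 and sham 11, 4 without sham 5 and 5 with edgeR. Without cPTAA 6, 7 and 9 and sham 8 there were 12 falls, and the rise was lost (0 rises). Adra1a and Adra1d, receptors for noradrenaline, were at 93.8 ± 36.96 against 695 ± 269.8 (log2 fold change -2.89 ± 0.32, adjusted p = 2.11e-05) and 79.8 ± 25.9 against 296 ± 107 (log2 fold change -1.88 ± 0.27, adjusted p = 0.000144). Among vascular tone receptors, channels and cGMP signalling genes, 3 of 20 rose and 11 fell (3 and 11 adjusted over the list alone), the rises being the receptors Ednra, Agtr1a and Adra1b. The vascular tone list had a camera adjusted p of 0.00147 (adjusted p = 0.148 with an estimated correlation). In the fit with the brown adipocyte score, 0 contractile genes fell, the contractile list lost its call (mean log2 change -0.03, adjusted p = 0.897, range 0.000103 to 0.00565), 0 vascular tone genes rose and 2 fell. The vascular tone list kept its lower call, with a mean log2 change of -0.70 against -0.60 without it (adjusted p = 0.00676, range 0.000611 to 0.0118). In that fit Myh11, Actg2 and Synpo2 no longer passed (log2 fold changes of -0.99, -0.54 and -1.24 against -1.305, -1.41 and -1.39 without it, adjusted p from 0.167 to 0.485, and at most 0.0506 under the other alternatives).

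**Figure D2:**
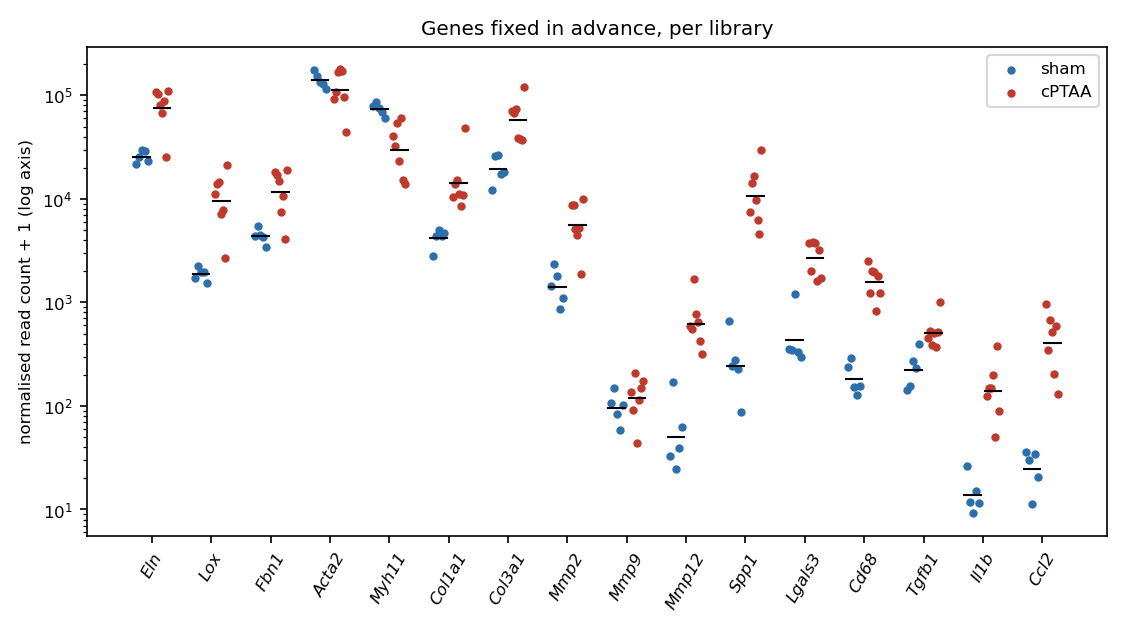
Normalised read counts + 1 on a log axis for the 16 panel genes, 1 point per library (sham in blue, cPTAA in red), with the geometric mean of each group as a bar. Acta2 and Mmp9 did not pass the test, and Spp1 had a mean of 12618 in cPTAA against 298 in sham.

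Genes of energy metabolism were lower. The respiratory chain genes Sdha and Ndufs1 were at 7419 ± 3018 against 20811 ± 5985 (log2 fold change -1.52 ± 0.26, adjusted p = 0.000718) and 1838 ± 870.3 against 4674 ± 1381 (log2 fold change -1.399 ± 0.27, adjusted p = 0.00148). Of the nuclear-encoded respiratory chain subunits, 0 of 41 rose and 36 fell (0 and 40 adjusted over the list alone). The respiratory chain list had a camera adjusted p of 7.84e-14 (adjusted p = 0.318 with an estimated correlation). The acyl-CoA dehydrogenases Acadvl and Acadl were at 2321 ± 1092 against 8988 ± 2756 (log2 fold change -2.01 ± 0.29, adjusted p = 0.000165) and 4181 ± 2708 against 15924 ± 4498 (log2 fold change -2.06 ± 0.33, adjusted p = 0.000358), and of the fatty acid oxidation genes 0 of 17 rose and 16 fell (0 and 16 adjusted over the list alone). The fatty acid oxidation list had a camera adjusted p of 3.23e-11 (adjusted p = 0.148 with an estimated correlation). In the mitochondrially encoded list 0 of 13 rose and 10 fell (0 and 12 adjusted over the list alone) (camera adjusted p = 2.55e-06, and adjusted p = 0.272 with an estimated correlation), and 6 fell without any one of cPTAA 2, cPTAA 3, sham 1, sham 10 and sham 11. Mitochondrial genes took 6.33 ± 4.15% of reads in cPTAA (SD, n = 7) and 13.98 ± 2.37% in sham (SD, n = 5). Pfkfb3, a regulator of glycolysis, was at 1821 ± 377 against 6828 ± 2059 (log2 fold change -1.86 ± 0.23, adjusted p = 4.61e-05). Of the glycolysis genes 0 of 17 rose and 5 fell (0 and 6 adjusted over the list alone) (camera adjusted p = 0.00486, and adjusted p = 0.434 with an estimated correlation), the falls being Hk2, Pfkl, Pfkp, Pgam1 and Pfkfb3. There were 10 falls without cPTAA 9 and 13 without cPTAA 6, 7 and 9 and sham 8. Under the brown adipocyte covariate, 0 respiratory chain, 0 fatty acid oxidation, 1 mitochondrially encoded and 1 glycolysis gene fell. The fatty acid oxidation list kept its lower call (mean log2 change -0.54 against -1.84 without it, adjusted p = 0.00591, range 9.52e-16 to 2.41e-09), and the mitochondrially encoded list lost its call (mean log2 change -0.17, adjusted p = 0.849, range 2.50e-10 to 1.58e-05). The respiratory chain and glycolysis lists were called higher by camera, with mean log2 changes of 0.21 (adjusted p = 0.0451, range 5.39e-29 to 9.89e-12) and 0.41 (adjusted p = 0.0331, range 4.07e-05 to 0.0192). Of their single genes, however, 0 rose there. In that fit Sdha, Ndufs1, Acadvl, Acadl and Pfkl no longer passed (log2 fold changes of -0.44, -0.24, -0.67, -0.71 and -0.17 against -1.52, -1.399, -2.01, -2.06 and -1.43 without it, adjusted p from 0.105 to 0.634, and at most 0.00634 under the other alternatives).

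Markers of brown and other adipocytes were lower in cPTAA. Brown adipocyte scores were 8.48 ± 1.10 in cPTAA (SD, n = 7) and 10.91 ± 0.65 in sham (SD, n = 5). Ucp1, the uncoupling protein, chosen after its values were seen, ranged from 105 to 28870 in cPTAA and from 16680 to 63200 in sham. Among the brown adipocyte markers 0 of 11 rose and 10 fell (0 and 10 adjusted over the list alone). The brown adipocyte list had a camera adjusted p of 1.03e-06 (adjusted p = 0.177 with an estimated correlation). Plin1, which coats lipid droplets, was at 3369.8 ± 841 against 9867 ± 2114 (log2 fold change -1.56 ± 0.19, adjusted p = 4.30e-05), and of the general adipocyte markers 0 of 15 rose and 12 fell (0 and 12 adjusted over the list alone) (camera adjusted p = 7.86e-08, and adjusted p = 0.148 with an estimated correlation), with 1 fall and no list call with the brown adipocyte score as a covariate (mean log2 change -0.38, adjusted p = 0.088, range 3.25e-09 to 8.09e-07).

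Fibroblast, endothelial and lymphatic genes moved in different directions. Thy1 and Meox1, of fibroblasts, were at 2571 ± 503 against 457 ± 113 (log2 fold change 2.500 ± 0.18, adjusted p = 2.22e-06) and 624.8 ± 194 against 109.7 ± 15.97 (log2 fold change 2.45 ± 0.21, adjusted p = 3.89e-06). Of the fibroblast markers 5 of 16 rose and 3 fell (7 and 3 adjusted over the list alone) (camera adjusted p = 0.0159, and adjusted p = 0.351 with an estimated correlation), the rises being Cd34, Tcf21, Fap, Thy1 and Meox1 and the falls Clec3b, Gsn and Lrrc15. There was 1 fall without sham 1 and there were 9 rises without cPTAA 6, 7 and 9 and sham 8. The growth factor genes Tgfb1, Tgfb2 and Bmp4 had log2 fold changes of 1.19 ± 0.27, 1.34 ± 0.28 and 1.79 ± 0.23. Of TGF-beta and BMP pathway genes 7 of 24 rose and 1 fell (7 and 1 adjusted over the list alone) (camera adjusted p = 0.0159, and adjusted p = 0.455 with an estimated correlation, and fry adjusted p = 0.0734), and the fall, Tgfbr3, a co-receptor, was lost (0 falls) without sham 1, 5, 8 or 10 or without cPTAA 6, 7 and 9 and sham 8. Flt1, a receptor for vascular endothelial growth factor, was at 834 ± 181 against 1653 ± 402 (log2 fold change -0.98 ± 0.20, adjusted p = 0.00216), while Ecscr was at 421 ± 52.3 against 226 ± 36.3 (log2 fold change 0.897 ± 0.14, adjusted p = 0.000371). Endothelial markers did not pass as a list, where 1 of 20 rose and 7 fell (3 and 7 adjusted over the list alone). The endothelial list had a camera adjusted p of 0.0712 (adjusted p = 0.474 with an estimated correlation). There were 4 falls without sham 11, 3 rises without cPTAA 4, without cPTAA 9 or without cPTAA 6, 7 and 9 and sham 8, and 2 without sham 8 or sham 11, by edgeR and with TMM scaling. The endothelial list passed without cPTAA 3 (adjusted p = 0.0345), cPTAA 12 (0.0432) or sham 8 (0.0246) and without cPTAA 6, 7 and 9 and sham 8 (0.0349), range 0.0246 to 0.146. Prox1, the transcription factor of lymphatic endothelium, was at 111 ± 17.7 against 15.1 ± 8.62 (log2 fold change 2.97 ± 0.33, adjusted p = 2.32e-05), and of the lymphatic markers 7 of 7 rose and 0 fell (7 and 0 adjusted over the list alone). The lymphatic list had a camera adjusted p of 1.63e-07 (adjusted p = 0.101 with an estimated correlation). With the brown adipocyte score as a covariate, 3 fibroblast, 1 TGF-beta and BMP and 2 lymphatic genes rose and 0 endothelial, fibroblast, TGF-beta or BMP genes fell. The fibroblast (mean log2 change 0.30, adjusted p = 0.136, range 0.00606 to 0.047) and TGF-beta (mean log2 change -0.08, adjusted p = 0.846, range 0.00105 to 0.0476) lists then lost their calls, while the lymphatic list kept its call, with a mean log2 change of 1.57 against 2.24 without it (adjusted p = 0.000154, range 8.61e-09 to 5.45e-06). In that fit Tgfb1, Tgfb2, Flt1 and Ecscr no longer passed (log2 fold changes of 0.54, 0.38, -0.80 and 0.84 against 1.19, 1.34, -0.98 and 0.897 without it, adjusted p from 0.0596 to 0.527, and at most 0.0182 under the other alternatives).

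Cartilage and bone genes were split. Runx2, a transcription factor of bone, was at 149 ± 87.6 against 23.8 ± 14.01 (log2 fold change 2.61 ± 0.45, adjusted p = 0.000665) and Col2a1, the cartilage collagen, at 1686 ± 2001 against 145 ± 281 (log2 fold change 4.67 ± 1.08, adjusted p = 0.00555), with an edgeR adjusted p for Col2a1 of 0.0564 in a range from 0.000329 to 0.0565. In that list 3 of 16 rose and 3 fell (4 and 4 adjusted over the list alone). The cartilage and bone list had a camera adjusted p of 0.637 (adjusted p = 0.881 with an estimated correlation). The rises were Runx2, Col2a1 and Ibsp and the falls Hapln1, Cytl1 and Snorc. Without sham 8, 7 rose, 8 without cPTAA 6, 7 and 9 and sham 8, and without cPTAA 3, cPTAA 4 or sham 11, 1 fell. Once the brown adipocyte score was a covariate 0 rose and 0 fell. In that fit Runx2 and Col2a1 no longer passed (log2 fold changes of 0.82 and 0.49 against 2.61 and 4.67 without it, adjusted p from 0.323 to 0.833, and at most 0.0565 under the other alternatives).

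Markers of neighbouring tissues differed between single libraries. The cardiac genes Myh6 and Actc1 reached 43560 and 47550 in cPTAA 9, and were also high in cPTAA 6 (5784 and 6040) and cPTAA 7 (10200 and 6902), against at most 2347 and 3199 in sham. Of 13 cardiac markers 0 rose and 0 fell by limma (0 and 0 adjusted over the list alone, 2 at an unadjusted p under 0.05), and edgeR called 1 higher (camera adjusted p = 0.941, and adjusted p = 0.979 with an estimated correlation). DESeq2 called the cardiac marker Myl7 lower (log2 fold change -1.62, adjusted p = 0.0436). In that list 1 fell without cPTAA 7 and 4 without cPTAA 6, 7 and 9 and sham 8, where the list was called lower (mean log2 change -1.54, adjusted p = 0.0241, range 0.0241 to 0.995). Under the brown adipocyte covariate it was called higher (adjusted p = 0.0372, range 0.0241 to 0.995), with 1 rise. Scgb1a1, of airway epithelium, was at 40500 in sham 8 and 3549.8 in sham 11, and at most 50.8 in cPTAA. Of the lung and airway markers 2 of 11 rose and 0 fell (2 and 0 adjusted over the list alone), the rises being Napsa and Rtkn2. The list's camera direction was up although its median (-0.33) and mean (-0.34) were below 0 (camera adjusted p = 0.722, and adjusted p = 0.889 with an estimated correlation), and 1 rose and 1 fell without sham 1. Lung rises numbered 4 without cPTAA 6, 7 and 9 and sham 8 and 1 by edgeR, and in the fit with the brown adipocyte score 0 rose and 1 fell, where Napsa no longer passed (log2 fold change of 2.92 against 3.85 without it, adjusted p = 0.0736, and at most 0.000784 under the other alternatives). The thymocyte genes Rag1 and Dntt reached 749.6 and 238 in cPTAA 3. Of the thymus list 0 of 6 rose and 0 fell (0 and 0 adjusted over the list alone) by limma (camera adjusted p = 0.181, and adjusted p = 0.62 with an estimated correlation), 2 having an unadjusted p under 0.05, and edgeR called 0 higher and 0 lower. There was 1 rise without cPTAA 4, without sham 1 or without cPTAA 6, 7 and 9 and sham 8, and there were 2 without sham 5. Myh6, Actc1, Scgb1a1, Rag1 and Dntt were chosen after their values were seen.

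Mesothelial, nerve and blood cell markers moved in part or not at all. Of the mesothelial markers 0 of 9 rose and 3 fell (0 and 3 adjusted over the list alone), the falls being Upk3b, Lrrn4 and Muc16 (camera adjusted p = 0.0159, and adjusted p = 0.434 with an estimated correlation), with 5 falls by edgeR. That list lost its call without cPTAA 6, 7 and 9 and sham 8 (adjusted p = 0.106, range 0.00499 to 0.106) and by fry (adjusted p = 0.0552). Of the Schwann cell markers 0 of 10 rose and 2 fell (0 and 1 adjusted over the list alone), the falls being Cdh19 and S100b (camera adjusted p = 0.124, and adjusted p = 0.62 with an estimated correlation). Schwann cell falls numbered 6 without cPTAA 12 and 1 without any one of cPTAA 2, 3, 4, 7 and 9 and sham 8, 10 and 11 or without cPTAA 6, 7 and 9 and sham 8, and 1 rose without sham 5. The Schwann cell list passed without cPTAA 12 (adjusted p = 0.0269) or sham 11 (0.0368), range 0.0269 to 0.431, and with the brown adipocyte score as a covariate (0.000231). Among autonomic neuron markers 1 of 9 rose and 0 fell (1 and 0 adjusted over the list alone), the rise being Uchl1 (camera adjusted p = 0.296, and adjusted p = 0.656 with an estimated correlation). It was lost (0 rises) without sham 5, 10 or 11 or without cPTAA 6, 7 and 9 and sham 8 (adjusted p of Uchl1 from 0.05 to 0.133, lowest 0.0014), while 2 fell without cPTAA 4 and 1 without cPTAA 12 or sham 5. For skeletal muscle 0 of 9 rose and 0 fell (0 and 0 adjusted over the list alone) by limma (camera adjusted p = 0.435, and adjusted p = 0.62 with an estimated correlation), with 0 at an unadjusted p under 0.05, 0 higher and 0 lower by edgeR, and 1 rise without sham 8 or without cPTAA 6, 7 and 9 and sham 8. For red blood cells 0 of 8 rose and 0 fell (0 and 0 adjusted over the list alone) by limma (camera adjusted p = 0.637, and adjusted p = 0.881 with an estimated correlation), with 1 at an unadjusted p under 0.05, 0 higher and 0 lower by edgeR, and 1 fall without cPTAA 9, without cPTAA 12 or without cPTAA 6, 7 and 9 and sham 8. That fall was in Car1, whose adjusted p was then 0.0207, 0.0273 and 0.0375 (range over its alternatives 0.0207 to 0.123). Car1 also passed with protein-coding genes only (adjusted p = 0.0489). Haemoglobin genes took at most 0.0976% of reads in cPTAA and 0.0457% in sham. For mast cells 1 of 9 rose and 0 fell (1 and 0 adjusted over the list alone), the rise being Fcer1a (camera adjusted p = 0.189, and adjusted p = 0.656 with an estimated correlation), with 2 rises without cPTAA 7 or without cPTAA 6, 7 and 9 and sham 8, where the list passed (adjusted p = 0.029, range 0.029 to 0.38). Among immediate early genes 5 of 18 rose and 2 fell (5 and 2 adjusted over the list alone), the rises being Junb, Egr2, Egr3, Ier3 and Myc and the falls Nr4a1 and Nr4a2 (camera adjusted p = 0.19, and adjusted p = 0.691 with an estimated correlation). In the fit with the brown adipocyte score 6 mesothelial genes fell, 0 mast cell genes rose, and 1 immediate early gene rose and 0 fell. The mesothelial list was lower there, with a mean log2 change of -2.88 against -1.26 without it (adjusted p = 8.60e-06, range 0.00499 to 0.106). There Cdh19 and Fcer1a no longer passed (log2 fold changes of -1.75 and 1.92 against -1.42 and 2.34 without it, adjusted p from 0.0784 to 0.253, and at most 0.0336 under the other alternatives). Without cPTAA 6, 7 and 9 and sham 8, 3 immediate early genes rose.

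Counted over the 45 lists, camera called 22 higher and 9 lower. With an estimated correlation, camera called 0 higher and 0 lower, and 12 higher and 1 lower at an unadjusted p under 0.05. By fry, which asks only whether the genes of a list moved one way, 20 were higher and 7 lower. Of 100 splits of the libraries into 7 and 5, the real one included, 9 gave as many camera calls as the real split. The other splits, which mixed the groups, gave from 2 to 35 calls. Some kept part of the real contrast, such as the one with 35 calls, which had 3 cPTAA libraries in its group of 7. Splits with 4 cPTAA libraries there, close to an even mix, gave from 2 to 28. Camera's p at the preset correlation therefore cannot be read as an error rate here.

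**Figure D3:**
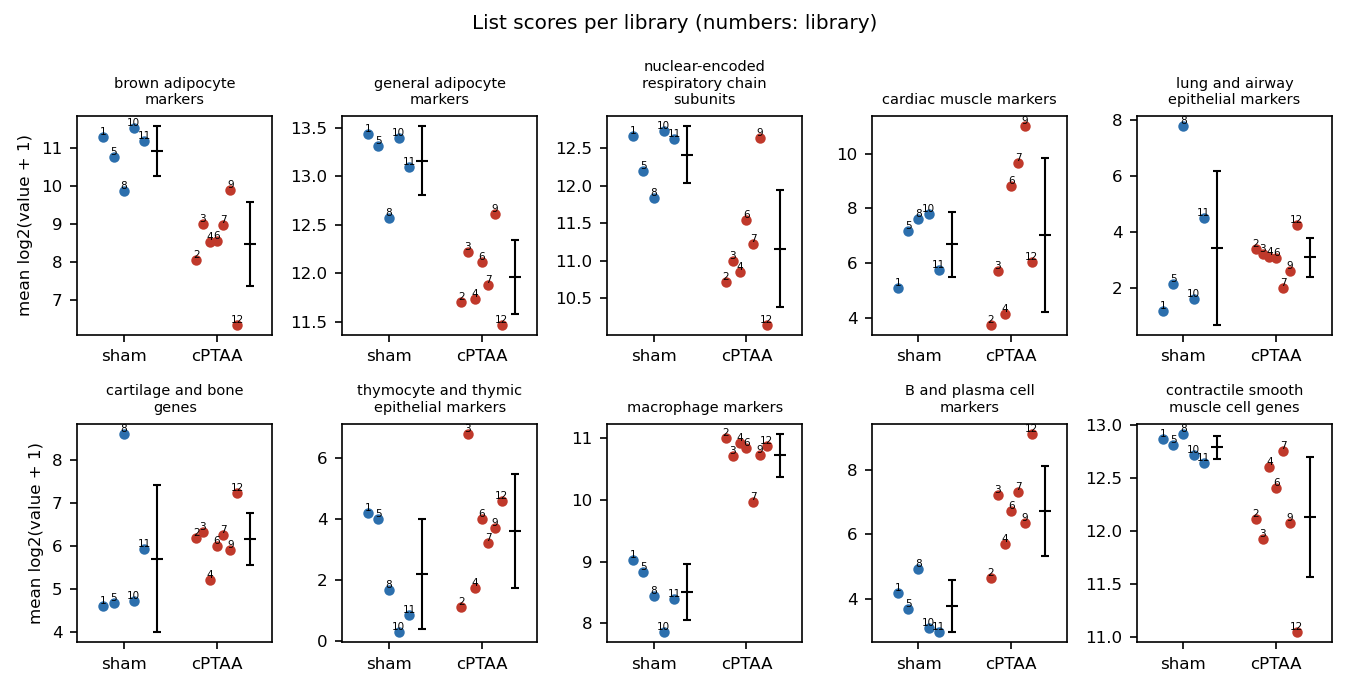
List scores (mean log2(value + 1) of the members) per library for 10 lists, with the group mean and SD beside the points and library numbers on them. Brown adipocyte scores were 8.48 ± 1.10 in cPTAA and 10.91 ± 0.65 in sham.

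Far fewer genes were shown to change by at least 2-fold. By limma's treat 624 rose and 91 fell. Among them Spp1 (treat adjusted p = 0.000166), Trem2 (0.000122), Timp1 (0.00019) and Cd68 (0.000404) rose, and Slc27a2 (0.00162), Adra1a (0.00164) and Sgk2 (0.000872) fell. Eln (treat adjusted p = 0.716), Col1a1 (0.346) and Col3a1 (0.62) were not shown to exceed 2-fold. The number of falls was 204 without cPTAA 9, 60 without sham 1, 60 without sham 5, 50 without sham 10, 52 without sham 11 and 430 without cPTAA 6, 7 and 9 and sham 8.

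Whether aneurysms varied more between libraries than sham aortas was tested on distances to the mean of the other libraries of the group. They were 56.6 ± 11.5 in cPTAA (SD, n = 7) and 67.9 ± 27.4 in sham (SD, n = 5). The difference of -11.3 was within the spread (exact two-sided permutation p = 0.41). A mean over fewer libraries lies farther off by construction, which enlarges the sham distances somewhat. The permutation moved finished distances between the groups, so its p does not allow for that. Sham 8 lay farthest, at 116, and without it the difference turned to 9.29 (exact permutation p = 0.221).

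Relations between list scores within the 7 cPTAA libraries did not pass after adjustment over the 4 computed. Contractile and fibrillar collagen scores gave r = -0.787 (exact permutation p = 0.0609, adjusted p = 0.244) and rho = -0.393 (exact permutation p = 0.396, adjusted p = 0.664), with r = 0.145 without cPTAA 12 and cPTAA 7, and r = -0.103 without cPTAA 12 alone (exact permutation p = 0.853), so its size rests on cPTAA 12. Its exact permutation p was 0.0444 without cPTAA 4 (r = -0.871) and 0.0292 without cPTAA 9 (r = -0.909), before adjustment. Contractile and macrophage scores gave r = -0.437 (exact permutation p = 0.271, adjusted p = 0.42) and rho = -0.107 (exact permutation p = 0.84, adjusted p = 0.84), with r = 0.489 without cPTAA 12 and cPTAA 7, and r was 0.110 without cPTAA 7 alone. Contractile and elastic fibre scores gave r = -0.318 (exact permutation p = 0.42, adjusted p = 0.42) and rho = -0.321 (exact permutation p = 0.498, adjusted p = 0.664), with r = 0.266 without cPTAA 12 and cPTAA 7. In that pair r was 0.194 without cPTAA 12 alone and -0.829 without cPTAA 9 (exact permutation p = 0.0389). Macrophage and protease scores gave r = 0.422 (exact permutation p = 0.351, adjusted p = 0.42) and rho = 0.679 (exact permutation p = 0.11, adjusted p = 0.44), with r = 0.631 without cPTAA 7 and cPTAA 2.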

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

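The tests of the brown adipocyte and cardiac scores in this part were chosen only after the results were seen. A library was singled out where its gap to the nearest other library of its group was a large share of the group's range by Dixon's test. This held in 44 of 298 groups of values. Chance flags about 1 in 20 groups where values are normally distributed, and values of one library are not independent of each other. Gene values were tested without a log, where skew can raise that share, so the 44 are not shown to exceed chance. Of the 44, 10 were in cPTAA 9, 9 in cPTAA 12 and 8 in sham 8. Values are given below against those of the nearest other library.

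In cPTAA 9 the energy metabolism genes stood highest in the cPTAA group: Sdha (13893 against 7668), Ndufs1 (3714 against 1884), Acadvl (4543 against 2593), Acadl (10115 against 4079.6) and Slc27a2 (785 against 227). It also stood apart in Myot, a muscle gene (185 against 50.2). Mitochondrial genes took 15.21% of its reads (Wilson 95% interval 15.20 to 15.23) against 7.35%, and its 10 most abundant genes 15.9% (15.88 to 15.92) against 10.1%. Its scores were lowest for elastic fibre genes (11.3 against 11.9) and lymphatic markers (8.78 against 9.35).

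For lower respiratory chain, fatty acid oxidation and mitochondrially encoded transcripts in cPTAA, less cardiac muscle is argued against as the whole cause: the cardiac score differed by 0.335 (95% interval -2.68 to 3.35), and its lowest limit times the upper limit of its slope gives changes of -0.920, -0.804 and -1.16 of the -1.26, -1.84 and -1.97 seen, with effects of -1.32 (-2.03 to -0.598), -1.89 (-2.54 to -1.25) and -2.05 (-2.90 to -1.21) beside it in the model. The unadjusted 95% intervals were -2.11 to -0.403, -2.59 to -1.09 and -3.04 to -0.910. For the respiratory chain and mitochondrially encoded lists they include the cardiac limit, so there the argument rests on the adjusted effects. Less brown fat remains a candidate explanation for the respiratory chain and mitochondrially encoded lists: with the brown adipocyte score in the model the group effects on the 3 scores were 0.211 (-0.560 to 0.983), -0.539 (-1.20 to 0.122) and -0.174 (-1.18 to 0.835). These intervals reached 0 because the effects shrank, though camera still called the fatty acid oxidation list lower (adjusted p = 0.00591), which leaves that list open, while the groups' brown adipocyte scores overlapped only in cPTAA 9 (9.89) and sham 8 (9.85) and the brown adipocyte list itself holds the respiratory chain genes Cox7a1 and Cox8b. Brown adipocyte markers fell more than general ones, since brown minus general adipocyte scores differed by -1.24 between the groups (exact permutation p = 0.00505). An equal loss of all adipocytes stays open, because general markers that other cells also express would fall less, and that was not tested. Whether the aneurysm samples held less brown fat or brown fat with a lower thermogenic program, and whether the disease or the dissection set it, stays open.

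In cPTAA 12 the highest values were in Col1a1 (48402 against 15194), Tgfb1 (1004 against 525), Runx2 (323 against 168), Col2a1 (5971 against 1866), Blk (299 against 100.4), Cd79b (614 against 182) and Dio3 (163 against 71.3). Its scores were highest for fibrillar collagens (12.4 against 10.99) and Schwann cell markers (7.73 against 6.50). In sham 8 the highest values were in Lgals3 (1208 against 356), Col2a1 (648 against 44.2), Hdc (457 against 131), Myl7 (369 against 133), Pycard (102 against 63.3), Capn13 (87.6 against 29.1) and Klrb1c (5.09 against 0), and Pfkfb3 was lowest there (3301 against 7148).

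Other libraries stood apart in fewer values. In cPTAA 2 these were Saa3 (6155 against 2199) and Hmox1 (2018 against 1174), in cPTAA 3 Cd8b1 (214 against 93.1) and Hoxb8 (9.89 against 3.69), in cPTAA 4 Mmp12 (1688 against 768), Itgax (815 against 479) and Capn13 (2.93 against 0.923) and in cPTAA 6 Uchl1 (4057 against 2126) and Ier3 (1750.1 against 859), each the highest. The macrophage score was lowest in cPTAA 7 (9.97 against 10.7). Among sham libraries the highest were mt-Nd4l (6949 against 2978) in sham 1, Mmp12 (170.4 against 61.7) in sham 5, Saa3 (22.8 against 6.98) and Ccr7 (18.4 against 6.11) in sham 10 and the haem and iron score in sham 11 (9.13 against 8.79). The lowest were Fkbp10 (801 against 976) in sham 1 and Cthrc1 (10.5 against 29.5) in sham 11.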

How the results depend on the processing

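The edgeR test with TMM, TMM scaling under limma, the fit without cPTAA 6, 7 and 9 and sham 8 and the brown adipocyte covariate were chosen only after the results were seen. The other alternatives were planned, and all of those were run. With the brown adipocyte covariate 663 genes rose (610 of them shared) and 374 fell (250 shared), and 5 lists were lower. There the sign turned for Acta2 (0.50) and Mmp9 (-0.0328), and camera's direction for the contractile (mean change -0.0316), TGF-beta (-0.0782), respiratory chain (0.211, adjusted p = 0.0451) and glycolysis lists (0.409, adjusted p = 0.0331). The cause was not tested beyond the scores weighed above. In that fit 35 of the named genes no longer passed, and of the other lists 5 lost and 3 gained a call, the brown adipocyte list losing its own by construction. With an estimated correlation camera called 0 lists higher and 0 lower, since the estimate widens its error, and fry lost 4 list calls. Without cPTAA 6, 7 and 9 and sham 8, 430 genes fell by at least 2-fold, and Myot (-0.78) and the cardiac list (-1.54) turned sign. The cause was not tested, though 3 of these libraries were left out for cardiac transcripts. Leaving out 1 library gave 2197 to 3163 rises and 1683 to 2825 falls, 474 to 691 and 50 to 204 of at least 2-fold, 22 lists higher each time and 9 to 11 lower. The difference in spread ranged from -19.1 to 9.29, and r from -0.591 to 0.110 for contractile and macrophage scores, -0.909 to -0.103 for contractile and fibrillar collagen, 0.323 to 0.691 for macrophage and proteases and -0.829 to 0.194 for contractile and elastic fibre, with fewer libraries as the only change. Of the named genes' results without 1 library, 1183 kept direction and side of the threshold, 11 lost and 6 gained a call. Of the lists' results 535 kept both and 5 gained a call. Under DESeq2 99 genes kept both, under edgeR with TMM 97, under TMM scaling 100, under voom 98 and under the stricter filter 96, of those tested there. The other planned settings each kept 97 to 99 genes. The median log2 fold change of all genes was -0.0325 with TMM. No paired analysis was possible because the library numbers of the groups do not overlap. With 200 changed genes, simulated 1.5-fold changes were not recovered at this depth and n. Far more genes were called in the real data, which makes the adjusted threshold less strict, so the simulation sets no limit there. Dnajb11, for example, passed at 1.68-fold (limma adjusted p = 0.000218).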

Other observations

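The gene sets and tests of this part, apart from the counts of other splits, were chosen only after the results were seen. Of immunoglobulin constant region genes, which share reads with close copies, and the joining chain gene, 10 of 10 rose, and 2 with the brown adipocyte score as a covariate. Ighg1, of the IgG class, was at 1365 ± 2165 against 1.30 ± 1.79 (log2 fold change 8.003 ± 0.95, adjusted p = 3.58e-05), and Igha at 1457 ± 1502 against 124 ± 219.9 (log2 fold change 4.405 ± 0.78, adjusted p = 0.000879). Of the Wnt ligands, targets and modulators, 8 rose and 3 fell of 14, the falls being Wnt5a, Wnt11 and Axin2. Wnt rises numbered 5 without sham 10 or sham 11, and 4 rose and 0 fell in the fit with the brown adipocyte score. Ccn5 was at 15884 ± 6062 against 1537 ± 379 (log2 fold change 3.32 ± 0.24, adjusted p = 2.22e-06) and the secreted Wnt antagonist Frzb at 3325 ± 1072 against 609.7 ± 153 (log2 fold change 2.42 ± 0.22, adjusted p = 6.08e-06), while Axin2, a target of Wnt signalling, was at 87.6 ± 26.7 against 160.04 ± 26.2 (log2 fold change -0.91 ± 0.23, adjusted p = 0.011). Of the lipogenesis genes 6 fell and 0 rose of 15, among them Dgat2, at 6694 ± 4939 against 23590 ± 6384 (log2 fold change -2.11 ± 0.46, adjusted p = 0.00392), and 0 fell with that covariate. Of 8 Notch receptors, ligands and targets 0 rose and 0 fell by limma, 1 had an unadjusted p under 0.05, and edgeR called 0 higher and 0 lower. Without cPTAA 9, 2 rose, and without cPTAA 6, 7 and 9 and sham 8, 3. Notch3 was at 781 ± 597 against 340.1 ± 121 (log2 fold change 0.98 ± 0.41, adjusted p = 0.1).

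Hox genes of groups 5 to 10, which mark position along the body axis, were lower in cPTAA: 8 fell and 1 rose of 15. All falls were in clusters a to c (8 of 12), and the rise, Hoxd9, was in cluster d. The number of falls was 5 without cPTAA 4, sham 1, sham 5 or sham 10 or without cPTAA 6, 7 and 9 and sham 8, and 2 with the brown adipocyte score as a covariate. The rise was lost (0 rises) without any one of cPTAA 3, 6, 7, 9 and 12 and the 5 sham libraries, and 2 rose without cPTAA 2. Hoxa5 was at 151 ± 25.4 against 419 ± 128 (log2 fold change -1.43 ± 0.19, adjusted p = 9.36e-05) and Hoxa7 at 31.3 ± 17.5 against 158 ± 79.4 (log2 fold change -2.302 ± 0.47, adjusted p = 0.00236). Of the Hox genes of groups 1 to 4, 1 fell of 9, namely Hoxc4, with 0 falls without sham 10 or without cPTAA 6, 7 and 9 and sham 8, and 2 without cPTAA 12 and by edgeR. The score of groups 5 to 10 was 3.30 in sham 11, within the cPTAA range of 2.74 to 4.09, and at least 4.55 in the other sham libraries.

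For these lower Hox genes an equal change of all Hox genes is argued against: after centring each library on the 21 with a mean of at least 10 in the higher group, their changes had an SD of 1.24 (exact permutation p = 0.00253). The score of groups 5 to 10 minus that of groups 1 to 4 differed by -0.721 (exact permutation p = 0.102). With the brown adipocyte score in the model the group effect was -1.60 (95% interval -3.20 to 0.00224) against -1.33 without it, so less brown fat may or may not account for it. Tissue taken at another position along the aorta, or other cells around it, was not tested.

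The fall of contractile genes was uneven, with Myh11 lower and Acta2 not past the test. An equal fall of all members is argued against, since after centring each library on the list the changes of its members had an SD of 0.586 (exact permutation p = 0.0139). Tagln, whose values are uncertain, was among these members, and the SD was not computed without it. Fewer smooth muscle cells alone stay open, because members that other cells also express would fall less, and that was not tested. Heart tissue stays open. Without cPTAA 6, 7 and 9 and sham 8 the SD was 0.530 (exact permutation p = 0.0286, the smallest that 70 splits can give), but there the cardiac list was lower in cPTAA (mean log2 change -1.54, adjusted p = 0.0241, range 0.0241 to 0.995). That difference came with leaving out the cPTAA libraries highest in cardiac transcripts, so this fit does not make the groups alike in heart tissue. Other cell types that express members such as Cald1, Sncg and Mcam stay open, and so does a change within smooth muscle cells.

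Other splits of the 12 libraries into 7 and 5 were counted, 100 in all with the real one. For the number of changed genes, 1 split, the real one, gave as many (5128, highest other 1247), and for changes of at least 2-fold 1 (715, highest other 0). Chance is thus unlikely for both, though 100 splits can show no share below 1 in 100. The split with 1247 had 2 cPTAA libraries in its group of 7, so it kept part of the real contrast. Such counts do not tell the disease from differences in the tissue taken. For the number of lists called by camera, 9 splits gave as many (31, highest other 35), so chance cannot be excluded for that number.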
